A study of Mus musculus with 8 samples.

How the data were processed

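Gene expression was measured in tibialis anterior muscle, a fast-twitch muscle of the lower hind limb, from 8 male C57BL/6J mice aged 14 weeks. Per the labels, 4 mice were controls and 4 had received Porphyromonas gingivalis, an anaerobic bacterium of the periodontal pocket, by mouth over 6 weeks from the age of 8 weeks. Per the labels' protocols the mice ate a high-fat diet, and the bacteria were given in a volume of 100 µL of saline through a feeding needle. What the control mice received, the bacterial dose and the sampling hour are not given in the sources used here. The protocol also uses group names that occur in no sample title, and these were not used. Labelled cRNA was made from 200 ng of total RNA per sample with 1 dye (Cy3), per the labels' protocols. Each sample is taken as 1 mouse, which the labels do not state outright. If samples shared a mouse, p-values would measure only the spread between samples.

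Each scanner file holds 59305 non-control spots of an Agilent expression array whose probe positions are given on the mm9 mouse genome build, per the file headers. The authors' deposited spot intensity values came from Agilent Feature Extraction, version 11.0.1.1 per the file headers and 11.1 per the submitters' processing notes. The processed intensity of a spot was background-subtracted and detrended within its array, with dim spots replaced by a surrogate value, per the file headers. It was not normalized between arrays. The authors also deposited a value table of log2 signals for 24764 probes, whose column medians lie between 7.357 and 7.374. Its columns have nearly the same quantiles, so a quantile normalization or one much like it had been applied. The exact scaling and the choice of probes are not given in the sources used here.

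The value table was matched to the scanner files by correlating each column with each array over probes, after each probe was centred on its own mean. Each column had 1 clear partner (correlations of 0.833 to 0.88, next best at most 0.0784), but only 2 of the 8 columns matched the array of the same label. Only 4 columns matched an array of the same group. Control 1, control 2, P. gingivalis 3 and P. gingivalis 4 were therefore the 4 arrays given the same group by both sources. Which source carries the right groups could not be settled from the labels or the files. All main results follow the scanner files, whose sample is recorded for each file, and arrays are named as the scanner files label them. Results with the groups of the value table are given beside the main counts.

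All 8 arrays lay on 1 slide and came from 1 scan, so no slide or scan effect could be fitted. The 4 control arrays filled slide row 1 and the 4 P. gingivalis arrays slide row 2, so slide row and group cannot be told apart. Array precision is limited by the number of arrays. Between 56.3% and 59.3% of spots were well above background, no spot was saturated, and between 0.108% and 0.218% of spots were left out as outliers.

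The processed intensities were put on the log2 scale, and each array's 75th percentile over non-control spots was subtracted. Spots of 1 probe were averaged on the log2 scale. Of 56605 distinct probes, 31649 were tested: those well above background on at least 4 of the 8 arrays, counting a probe as such when over 50% of its spots were. Probes were named through the RefSeq table of mouse assembly GRCm38.p6, used for names only: 32994 by the accession of the probe, 895 by another accession listed for it and 9951 by a current symbol or an unambiguous synonym. Another 12765 probes had no current gene name. A gene was represented by its tested probe with the highest mean signal over the 8 arrays, giving 16034 genes.

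Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate), with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Fold changes are P. gingivalis over control, and errors are standard errors of the log2 difference or 95% confidence intervals from the same fit. There were 28 gene lists, 16 of pathways and 12 of cell type markers, all fixed before the data were examined. They were tested with camera at its preset correlation of 0.01, adjusted over the 28 lists, with camera at an estimated correlation and fry beside it. A list score is the mean over a list's genes of the log2 signal centred on each gene's mean. The scores of both groups were compared with a two-sided exact permutation test over the 70 assignments of 8 arrays, whose smallest p is 0.0286. Figures were drawn with matplotlib 3.10.9.

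The genes named were fixed by rule at the same time as the lists. In each direction 12 genes were to be named among those past the adjusted threshold with non-overlapping groups, filled where too few passed with the lowest unadjusted p at an absolute log2 change of at least 0.5. Predicted symbols were passed over in filling. From each list the rule took the 3 genes of lowest p, with any that passed adjusted over the list alone, and not all of these are given in the text. Slc2a4, Irs1, Insr, Tnf, Il6, Il1b, Ccl2, Fbxo32, Trim63, Ppargc1a and Pdk4 were always to be given. Of probes well above background on all arrays of 1 group and none of the other, the 5 with the largest bound in each direction were named. For these a bound was computed: the bright group's mean against the dim group's mean of, per array, the higher of the probe's own value and the lowest value well above background. A bound is on the means of these arrays and holds no sampling error, so the difference between the groups could be smaller. A gene outside the rule is said to be so where it is named.

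Simulated arrays, 4 against 4, held independent normal values with the means of 31641 real probes and their spreads as shrunk by eBayes. The fit was tested on these, with 50 probes changed at each fold. It recovered 54% of probes changed 1.5-fold, 84% at 2-fold, 98% at 3-fold and 100% at 4-fold, with 8 false calls. Shrunken spreads vary less than real ones, and probes of all folds were changed at once, which eases the adjustment. Recovery in the real data may therefore be lower. In the same design a list shifted by 0.3 on the log2 scale was recovered, and no other list passed. As genes were drawn independently, this cannot show how often lists of correlated genes pass by chance. Estimated correlations of the real lists reached 0.982, for skin keratinocyte genes, and were 0.67 for interferon response genes. The alternatives tried were quantile normalization, median centring, normexp background correction, no filter or a stricter filter on dim probes, the value table, a block for replicate number, an intensity trend, array weights, another detection flag, the mean of all probes of a gene, and leaving out each array. The normexp correction added an offset of 50 to each signal. A block for slide could not be fitted, since there was 1 slide. Alternatives on the mismatch between the sources were chosen after the data were seen.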

Results

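Cy3 signals were collected from 8 arrays of mouse tibialis anterior muscle, 4 from control mice and 4 from mice given P. gingivalis by mouth for 6 weeks. The comparison asks which muscle transcripts differ after oral administration of the bacterium. The arrays were alike, with correlations of 0.9909 to 0.9949 between arrays over tested probes. Each control array was brighter before scaling than each P. gingivalis array. The 75th percentile of the processed signal ran from 275 to 306 in the controls and from 238 to 255 in the P. gingivalis arrays (two-sided exact permutation p = 0.0286, the smallest possible here). The controls filled 1 row of the slide and the P. gingivalis arrays the other. The groups below are those of the scanner files. The deposited value table gives 4 of the 8 arrays the other group, so directions below are given for the groups of the scanner files. With those of the value table, 6 of the 10 lists called below kept their direction and 0 their call.

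**Figure D1:**
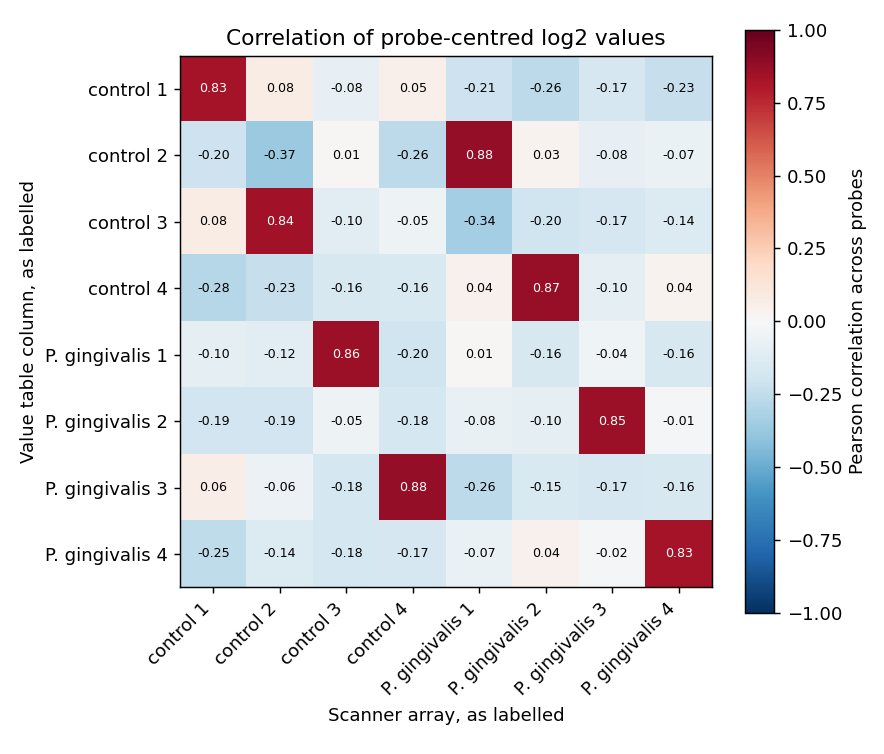
Pearson correlation across probes of each value table column (rows, as labelled) with each scanner array (columns, as labelled), after each probe was centred on its mean. Each row has 1 dark red cell, at 0.83 to 0.88, and only control 1 and P. gingivalis 4 have it on the diagonal.

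No transcript passed the adjusted threshold. Dct, dopachrome tautomerase of melanin synthesis, had the lowest p, with a signal 2.02-fold higher in P. gingivalis muscle (95% confidence interval 1.71 to 2.39, adjusted p = 0.254 by limma). Its probe lies on chromosome 14 from 118442262 to 118442321 (mm9). Cxcl1, a chemokine that attracts neutrophils, was well above background on all 4 control arrays and on none of the P. gingivalis arrays. Its array means differed at least 2.21-fold, higher in control muscle (adjusted p = 0.304 by limma). Its probe lies on chromosome 5 from 91322080 to 91322139 (mm9). Nr1d1, which encodes the clock repressor REV-ERBα, stood at 1.43 ± 0.15 in control and 0.87 ± 0.10 in P. gingivalis muscle (log2 signal relative to the 75th percentile, SD, n = 4 each). Its probe lies on chromosome 11 from 98630526 to 98631028 (mm9).

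By limma, 0 of 31649 tested probes passed an adjusted p of 0.05, while 3527 had an unadjusted p under 0.05. At p under 0.01 there were 930 probes, 507 higher and 423 lower in P. gingivalis muscle, where chance would give 316. With the groups of the value table the same arrays gave 213. Of 16034 genes, 1124 had groups that did not overlap, or 7.01% against the 2.86% that chance gives. Normexp background correction raised the count at p under 0.01 to 3556, of which 80.8% were higher in P. gingivalis muscle against 54.5% without it, and 14 probes then passed adjustment. The offset of that correction exceeded each array's median processed signal (15.8 to 21.1), and the P. gingivalis arrays were then scaled by a lower 75th percentile. This can lift dim probes in the P. gingivalis arrays, and its part in these counts was not tested. An intensity trend in the variance called 2 probes, Dct (adjusted p = 0.00591 by limma) and Gm31704, and testing all probes without a filter called 2, Olfr774 and Tfr2. The value table under its own labels gave 134 probes at p under 0.01 and 0 past adjustment.

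**Figure D2:**
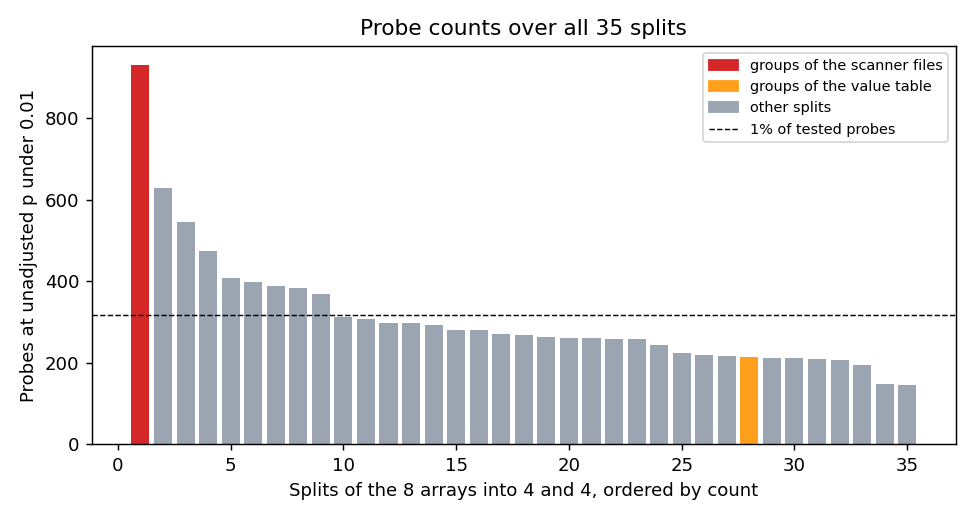
Probes at an unadjusted p under 0.01 (vertical axis) for each of the 35 splits of the 8 arrays into 4 and 4, ordered by count, with the groups of the scanner files in red, those of the value table in orange and a dashed line at 1% of tested probes. The groups of the scanner files gave 930 and the highest other split 629. The groups of the value table ranked 28 of 35, with 213.

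None of the 24 genes named by the rule passed adjustment, and the adjusted p was 0.304 for each except Dct. Among the 12 with higher signal in P. gingivalis muscle, Mc3r, the melanocortin 3 receptor, was well above background on only 2 control arrays, so no size is given for its difference. Gsta3, a glutathione transferase, differed 1.92-fold (interval 1.43 to 2.56) and did so on both of its probes. Pde8a, a cAMP phosphodiesterase, was well above background on no control array, and its array means differed at least 1.58-fold, higher in P. gingivalis muscle. Dpp4, the peptidase that cleaves incretin hormones, differed 1.52-fold on its brighter probe, while its other probe went the opposite way (log2 change −0.28). Cmtm2b differed 1.52-fold, Mmrn1 1.51-fold, Cfc1 1.45-fold, Wee1, a kinase that restrains entry into mitosis, 1.43-fold, and Mras, a Ras-family GTPase, 1.42-fold. Igsf1 and Cacna1b, a calcium channel subunit, each differed 1.42-fold, and the dimmest probe of either showed no such difference (log2 changes −0.09 and −0.05).

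Among the 12 with lower signal in P. gingivalis muscle, Sapcd2 was well above background on all control and no P. gingivalis arrays. Its array means differed at least 1.57-fold, higher in controls. Dusp2, a phosphatase of MAP kinases, differed by −0.86 ± 0.18 on the log2 scale (SE). Cd164l2 differed by −0.80, with a second probe at 0.11. Olfr316, an olfactory receptor gene, was well above background on only 1 P. gingivalis array, so no size is given for its difference. Pip5k1b, a phosphoinositide kinase, differed by −0.71 and was well above background on only 3 P. gingivalis arrays. Six4, a homeobox gene of muscle development, was at −0.60 and −0.33 on its 2 probes. Ret, a receptor of glial cell line-derived neurotrophic factors, differed by −0.59, Adam32 by −0.57 and Tmem144 by −0.51. Tbc1d4, a Rab GTPase-activating protein through which insulin signalling releases the glucose transporter GLUT4, differed by −0.50, −0.52 and −0.44 on its 3 probes. Under normexp correction Olfr316, Sapcd2 and Pip5k1b changed sign.

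**Figure D3:**
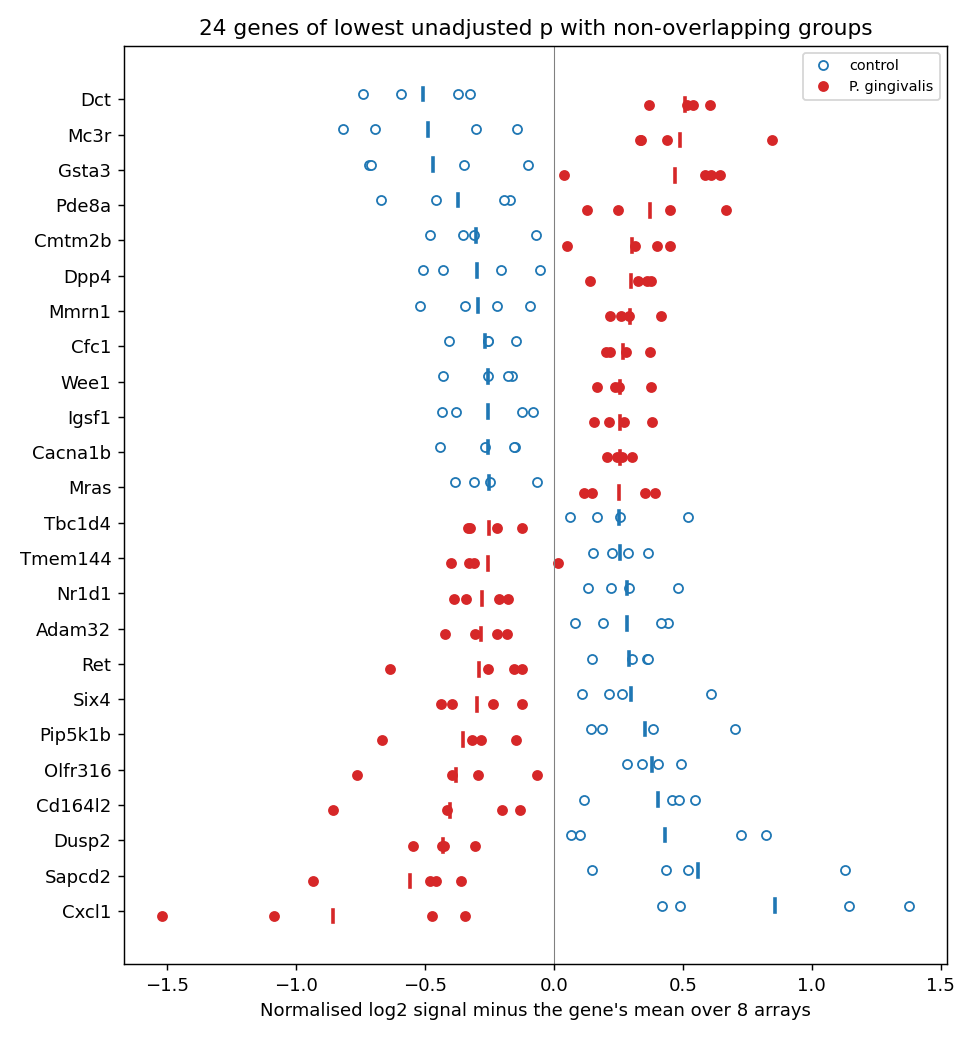
Normalised log2 signal of the 24 genes on each array, minus the gene's mean over the 8 arrays, with control arrays as open blue circles, P. gingivalis arrays as filled red circles and vertical bars for the group means. The groups are separate for each gene, with Dct at a log2 difference of 1.02. Cxcl1 and Sapcd2 were not well above background on any P. gingivalis array, nor Pde8a on any control array, so their plotted distances are no measure of the fold. Nor are those of Mc3r, well above background on 2 control arrays, and Olfr316, on 1 P. gingivalis array.

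Of the 28 gene lists, 10 passed camera's adjusted threshold at its preset correlation, 7 higher and 3 lower in P. gingivalis muscle. Higher lists were fast fibre, extracellular matrix, tendon, fibroblast, glucocorticoid response, macrophage and glycolysis genes, and lower lists were endothelial, immediate early and fatty acid oxidation genes. None passed with an estimated correlation, where the lowest adjusted p was 0.468, and none passed by fry's directional test. By fry's mixed test, which asks whether a list's genes change in either direction, 8 passed. They were fast fibre, glycolysis, fatty acid oxidation, immediate early, circadian clock, neutrophil, TNF and NF-kB response and insulin signalling genes. Extracellular matrix, tendon, fibroblast, glucocorticoid response, macrophage and endothelial genes did not pass that test. The exact permutation test on list scores gave 2 lists at the smallest p it allows, fast fibre and TNF and NF-kB response, where chance gives 0.8, and none passed after adjustment. With the groups of the value table, 0 of the 10 passed in the same direction. The count fell to 6 without control 4, to 5 without P. gingivalis 1 and to 6 without P. gingivalis 2.

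**Figure D4:**
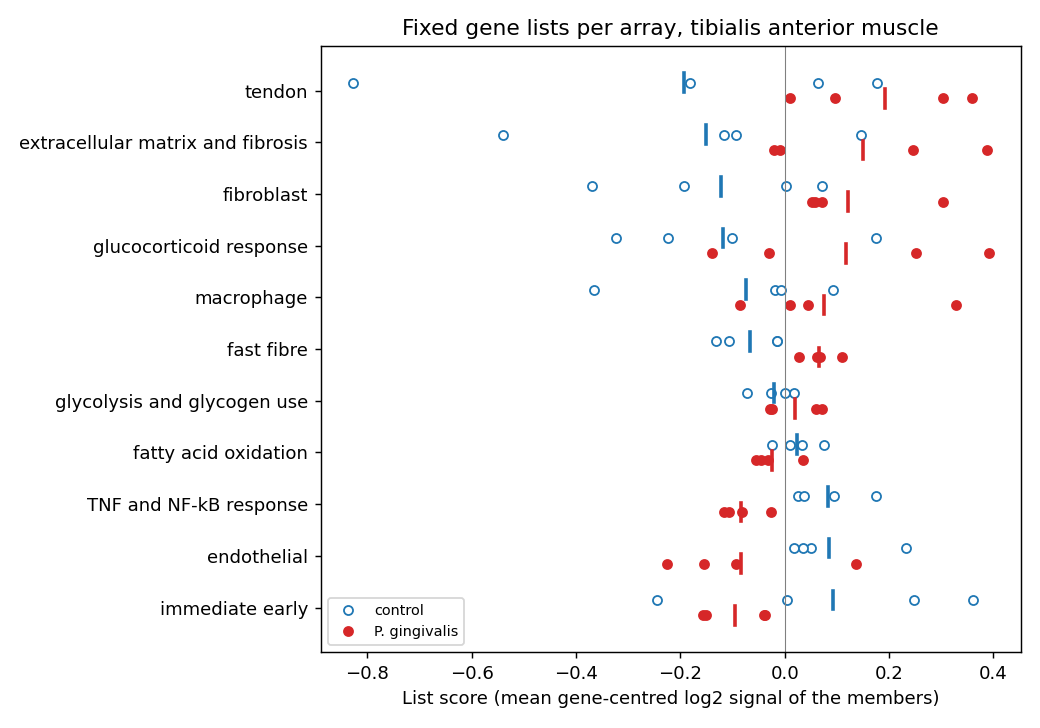
List scores of the 11 lists past camera's adjusted threshold or the exact test, as the mean gene-centred log2 signal on each array, with controls as open blue circles, P. gingivalis arrays as filled red circles and vertical bars for the group means. The groups are separate for fast fibre (difference 0.133) and TNF and NF-kB response (−0.165), and overlap for the other 9 lists.

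Collagens and other matrix genes stood higher in P. gingivalis muscle. Of 19 extracellular matrix and fibrosis genes, 16 were higher and 3 lower, the mean log2 change was 0.30, and camera's adjusted p was 0.00392, with an unadjusted p of 0.298 at an estimated correlation. Adjusted over the list alone, 5 genes were higher and 1 lower, against 0 adjusted over all probes. Col1a1 and Col3a1, the main fibrillar collagens with Col1a2, differed 2.04-fold (interval 1.28 to 3.23) and 1.95-fold, and all 3 Col1a1 probes agreed in direction. Col1a2 differed 1.57-fold, Mmp2, a matrix metalloproteinase, 1.54-fold and Col6a1 1.48-fold. Col15a1, a collagen of basement membranes, was the lower gene, but it was well above background on only 1 P. gingivalis array, so no size is given. It also changed sign under normexp. The list's score was lowest in control 2 (−0.54, other controls −0.12 to 0.15), and without control 2 the mean was 0.17 (adjusted p = 0.0226). The call was lost without P. gingivalis 1 (mean 0.22, adjusted p = 0.072).

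Markers of matrix-making cells went the same way. All 5 tested tendon genes were higher (mean 0.39, adjusted p = 0.0204 by camera, p = 0.156 with an estimated correlation), with Thbs4 at the lowest p (1.35-fold), Scx at 0.21 and Fmod at 0.33. Of 8 fibroblast genes 7 were higher (mean 0.24, adjusted p = 0.0127, p = 0.162 with an estimated correlation). Lum, the proteoglycan lumican, differed 1.59-fold and alone passed adjusted over the list alone, with Gsn at 0.29 and Dpt at 0.38. Control 2 had the lowest scores here too, −0.83 for tendon and −0.37 for fibroblast genes, and without control 2 both calls were lost (means of 0.17 and 0.16, adjusted p = 0.147 for tendon and 0.0688 for fibroblast genes). The fibroblast call was also lost without P. gingivalis 1 (adjusted p = 0.0727) and the tendon call without P. gingivalis 2 (adjusted p = 0.0606). Neither passed under normexp correction (adjusted p = 0.14 for fibroblast and 0.11 for tendon genes) or without a filter (0.0619 and 0.0809).

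Fast-twitch contractile genes stood slightly higher in P. gingivalis muscle. Of 13 fast fibre genes 12 were higher (mean 0.13), camera's adjusted p was 7.2e-05, and the list scores of the groups did not overlap (exact permutation p = 0.0286). The p with an estimated correlation was 0.0603. Myl1, a fast myosin light chain, differed 1.20-fold and alone passed adjusted over the list alone, while its 3 dimmer probes stood at 0.16, 0.05 and −0.02, with Mylpf at 0.17 and Tnni2 at 0.17. Quantile normalization ended the call (mean 0.04, adjusted p = 0.189), as did normexp correction (mean 0.08, adjusted p = 0.11) and the matched columns of the value table (mean 0.04, adjusted p = 0.275). The 100 brightest probes held 11.7% to 12.5% of the signal on control arrays and 12.9% to 13.1% on P. gingivalis arrays. Quantile normalization gives all arrays the same distribution of signals, and it lowered both this mean and that of the glycolysis list (−0.0227). Such a difference in scale among bright probes may therefore have contributed to both lists, and slide row could share in it. Quantile normalization would also remove a true rise shared by the brightest genes, so it cannot tell these apart. Slow fibre genes did not pass (mean 0.12, adjusted p = 0.464), with array scores from −0.42 to 0.48 and Myl3 at 0.11, Myoz2 at 0.21 and Tnnt1 at 0.22. Their mean turned to −0.02 without P. gingivalis 2.

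Glycolytic genes showed a small shift and fatty acid oxidation genes the opposite one. Of 18 glycolysis and glycogen genes 15 were higher (mean 0.04, adjusted p = 0.0127 by camera, p = 0.0818 with an estimated correlation), with Aldoa at 0.17, Gapdh at 0.15 and Pfkfb1 at 0.22. The mean turned to −0.02 under quantile normalization and −0.01 under normexp, and the call was lost without P. gingivalis 3 (mean 0.0227, adjusted p = 0.052). It was also lost without a filter (adjusted p = 0.0653), with the matched columns of the value table (mean 0.01, adjusted p = 0.277) and on the 4 arrays given the same group by both sources (adjusted p = 0.128). Without control 3 or P. gingivalis 4 the mean was 0.0223 and 0.0261. Of 25 fatty acid oxidation genes 18 were lower (mean −0.05, adjusted p = 0.031, p = 0.167 with an estimated correlation), with Acot2 at −0.41 and Ppard at −0.21, while Ucp3, a mitochondrial carrier, stood at 0.27. That call was lost without control 1, control 4, P. gingivalis 2 or P. gingivalis 4 (adjusted p of 0.114, 0.103, 0.143 and 0.0544), with a mean of −0.03 without control 1. It was lost too with the matched columns (adjusted p = 0.0804) and on those 4 arrays (adjusted p = 0.236). Oxidative phosphorylation genes (mean 0.02, adjusted p = 0.49) and lipid synthesis and storage genes (mean −0.02, adjusted p = 0.243) did not pass. The oxidative phosphorylation mean turned to −0.02 under quantile normalization and −0.04 under normexp. Sdhd stood at −0.10, Atp5b at 0.13 and Sdha at 0.09 in the former, and Dgat2 at −0.21, Acacb at −0.13 and Agpat2 at −0.17 in the latter.

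Insulin signalling genes as a group did not pass camera, but passed fry's mixed test (adjusted p = 0.0404). Of 22 genes 11 were higher and 11 lower (mean −0.0011, median 0.0021, adjusted p = 0.9 by camera), and only Tbc1d4 passed adjusted over the list alone (adjusted p = 0.0283 by limma), in the lower direction. Its relative Tbc1d1 stood at 0.25, −0.20 and 0.38 on its 3 probes, and Irs2 at −0.28. Slc2a4, which encodes GLUT4, was at 8.02 ± 0.12 in control and 8.10 ± 0.07 in P. gingivalis muscle (log2, SD, n = 4 each). The log2 changes of Irs1 (−0.10 ± 0.18, SE), Insr (−0.01), Ppargc1a (−0.01) and Pdk4 (−0.01) were within the spread between arrays.

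Atrophy and denervation genes did not pass. The 18 atrophy genes had a mean change of 0.07 and a median of 0.03, with camera's direction lower (adjusted p = 0.8). With the groups of the value table the mean was −0.21 (adjusted p = 0.00362), and without P. gingivalis 1 it was −0.02. The ubiquitin ligase genes Fbxo32 and Trim63 stood at −0.24 and 0.01, and Foxo3 at 0.23. Ddit4, a stress-induced inhibitor of mTORC1, stood at 0.93, with an interval of 0.972-fold to 3.75-fold that includes no change. Of 12 tested denervation and regeneration genes 8 were higher (mean 0.10, adjusted p = 0.212), with Myh8 at 0.24, Ncam1 at 0.27 and Hdac4 at 0.20. The Myh8 probe was brighter in control muscle (9.81) than that of the fast fibre myosin gene Myh4 (9.60). Whether it reads Myh8 alone was not tested.

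Neither inflammatory response list passed camera, though each did under some alternatives. Of 25 tested TNF and NF-kB response genes 17 were lower (mean −0.17, median −0.05, adjusted p = 0.0671 by camera). With an estimated correlation camera's p was 0.0483, the only one of the 28 lists under 0.05, and 0.468 after adjustment. Fry's mixed test passed (adjusted p = 0.0351). In the value table the mean was 0.004 under its own labels (adjusted p = 0.952) and −0.09 with its columns matched to the scanner files (adjusted p = 0.0397). The list's score was lower in all 4 P. gingivalis arrays (exact permutation p = 0.0286, adjusted 0.4). Camera at its preset correlation also passed without control 1 (adjusted p = 0.0408), without P. gingivalis 3 (0.0442) and without a filter (0.0115). Cxcl1 and Icam1, an adhesion molecule for leukocytes at −0.57, passed adjusted over the list alone, and Tnfaip3 stood at −0.35. The log2 changes of the chemokine gene Ccl2 (−0.79 ± 0.45, SE) and the cytokine gene Tnf (−0.07) were within the spread between arrays. Ccl2 was well above background on only 3 P. gingivalis arrays. The cytokine gene Il6 was so on 4 control and only 2 P. gingivalis arrays, so no size is given for its difference. The 3 probes of Il1b were not well above background on any array. The 22 interferon response genes did not pass (mean −0.12, adjusted p = 0.077, exact permutation p = 0.686, p = 0.568 with an estimated correlation), with Bst2 at −0.28 and Stat2 at −0.26. Control 2 had the highest interferon score, 0.50 against −0.22 to 0.12 in the other 7 arrays. Without control 2 the mean turned to 0.03 (adjusted p = 0.8), while the list passed at the preset correlation without control 1, control 3 or P. gingivalis 4 (adjusted p of 0.00174, 0.00946 and 0.0185), and without a filter (0.0243).

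S100a8 and S100a9, which encode the calcium-binding proteins of the neutrophil cytosol, had lower signal in P. gingivalis muscle than in most controls. The S100a9 signal was at 0.55 ± 1.76 in control and −2.37 ± 0.68 in P. gingivalis muscle (log2, SD, n = 4 each), a 7.54-fold difference with an interval of 2.11 to 26.9. S100a8 was well above background on 4 control and only 2 P. gingivalis arrays, so no size is given for its difference. Control 3 stood with the P. gingivalis arrays for both genes, at −2.06 for S100a9 against 1.22 to 1.78 in the other controls. Both genes passed adjusted over the list alone (adjusted p = 0.0173 each by limma), in the lower direction, and neither did over all probes. Elane, neutrophil elastase, passed adjusted over the list alone in the higher direction, 1.30-fold. The list of 7 tested neutrophil genes did not pass camera or the exact test (mean −0.92, median −0.12, adjusted p = 0.232 by camera, exact permutation p = 0.0857). It passed fry's mixed test (adjusted p = 0.0107), and camera on the 4 arrays given the same group by both sources (mean −1.35, adjusted p = 0.0185). Control 3 is not among those 4 arrays, which could enlarge the difference.

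Macrophage markers passed camera and lymphocyte markers did not. Of 14 macrophage genes 11 were higher (mean 0.15, adjusted p = 0.0212, p = 0.342 with an estimated correlation), with Csf1r at 0.37 and Cd163 at 0.66, and Itgam at 0.19 with its dimmer probe at −0.57. The call was lost without control 1 (mean 0.05, adjusted p = 0.28) or P. gingivalis 1 (mean 0.06, adjusted p = 0.3), and under normexp correction (adjusted p = 0.0941), without a filter (0.176) and on the 4 arrays given the same group by both sources (0.116). The 7 tested lymphocyte genes had a mean of 0.04 (adjusted p = 0.9), with Ms4a1 at 0.34, Cd4 at −0.21 and Cd79b at 0.32.

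Glucocorticoid response genes stood higher and immediate early genes lower in P. gingivalis muscle. Of 10 glucocorticoid response genes 9 were higher (mean 0.24, adjusted p = 0.0127 by camera, p = 0.287 with an estimated correlation). Tsc22d3, a glucocorticoid-induced leucine zipper gene, stood at 0.40, Fkbp5 at 0.46 and Zbtb16 at 0.24. That call was lost without control 1, control 4, P. gingivalis 1 or P. gingivalis 2 (adjusted p of 0.1, 0.0582, 0.116 and 0.0606), with a mean of 0.15 without P. gingivalis 1, under normexp correction (adjusted p = 0.146) and without a filter (0.0653). Of 17 immediate early genes 12 were lower (mean −0.19, adjusted p = 0.0127, p = 0.124 with an estimated correlation), with Junb at −0.26, Fosb at −0.54 and Klf4 at −0.26, and the call was lost without control 3 (mean −0.10, adjusted p = 0.0675) or control 4 (adjusted p = 0.106), while without control 2 the mean was −0.30. On the 4 arrays given the same group by both sources it was −0.04 (adjusted p = 0.521). Camera read 16 of the 17, since 1 had a left-out spot. The 17 tested circadian genes did not pass camera (mean −0.003, median 0.05, adjusted p = 0.9) but passed fry's mixed test (adjusted p = 0.0107). Nr1d1 alone passed adjusted over the list alone (adjusted p = 0.00366 by limma), with Nfil3 at 0.52 and Bhlhe40 at −0.27. The 17 heat shock and unfolded protein response genes did not pass (mean −0.03, adjusted p = 0.502), with Pdia4 at 0.28, Hsp90aa1 at −0.24 and Hspa5 at 0.14.

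Some endothelial markers stood lower in P. gingivalis muscle. Of 10 genes 9 were lower (mean −0.17, median −0.08, adjusted p = 0.0127 by camera, p = 0.231 with an estimated correlation). Kdr, the main receptor of vascular endothelial growth factor, stood at −0.57 and alone passed adjusted over the list alone, with Cldn5 at −0.42 and Egfl7 at −0.29. Control 4 had the highest score, 0.23 against 0.02 to 0.05 in the other controls, and the call was lost without control 4, P. gingivalis 1 or P. gingivalis 2 (adjusted p of 0.149, 0.0936 and 0.0563). With the groups of the value table the list was higher instead (mean 0.16, adjusted p = 0.000154), and on the 4 arrays given the same group by both sources the mean was −0.01 (adjusted p = 0.989).

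Other cell type markers did not pass. Smooth muscle and pericyte genes had a mean of 0.03 (adjusted p = 0.47), with Acta2 at 0.17, Cnn1 at −0.35 and Myh11 at 0.18. The dimmer Acta2 probes stood at 0.02 and −0.12. Schwann cell genes had a mean of −0.01 and a median of 0.01 (adjusted p = 0.83), with Mbp at −0.34 on its brightest and 0.32 on its dimmest probe, and Sox10 at 0.09. Satellite cell genes had a mean of −0.06 (adjusted p = 0.528), with Chrdl2 at −0.44, Cdh15 at −0.07 and Sdc4 at 0.11. Adipocyte genes had a mean of −0.06 and a median of 0.02 (adjusted p = 0.464), with Fabp4 at −0.22, Pparg at −0.17 and Lep at 0.13. The adipocyte mean turned to 0.05 without control 3, 0.04 without P. gingivalis 2 and 0.09 without P. gingivalis 4. Erythroid genes had a mean of −0.04 (adjusted p = 0.785), with Hba-a1 at −0.11, Alas2 at −0.11 and Hbb-bt at −0.05. The erythroid mean was 0.04 without control 2, 0.02 without P. gingivalis 2 and 0.21 in the value table under its own labels (adjusted p = 0.00635 by camera). Skin keratinocyte genes had a mean of −1.14 (adjusted p = 0.232) that rested on control 4 and was 0.12 without it. There Krt5, Krt14 and Lor stood at 1.21, 1.91 and 3.21 against −2.76, −3.94 and −4.26 or less in the other controls.

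Some probes crossed the background in 1 group only. On all 4 arrays of 1 group and none of the other, 35 probes were well above background, 5 in P. gingivalis muscle and 30 in controls, whose arrays were brighter before scaling. In array means, Lrch3 and Scamp5 were at least 1.59-fold and 1.54-fold higher in P. gingivalis muscle at these probes. The unnamed transcripts 1700038P13Rik and C78228 were at least 1.87-fold and 1.79-fold higher in the same way. Lrch3, Scamp5 and Atp6v1h each had another probe above background, so for them only the probe is concerned. After Cxcl1, the largest bounds in controls were those of the unnamed transcript AK083840 (at least 1.64-fold), Nppc, which encodes C-type natriuretic peptide (1.63-fold), Sapcd2 and Atp6v1h, a subunit of the vacuolar proton pump (1.49-fold). None passed adjustment by limma, and with the groups of the value table the count was 13. Leaving out 1 array at a time, which asks fewer arrays to meet the rule, gave 53 to 104.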

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

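The counts over splits of the arrays, both tests on the value table and the test on faulty spots were chosen after the results were seen, and those on slide row, GC content, dim probes and skin after their patterns but before their own results.

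In 7 of 128 sets of 4 arrays, 1 array stood apart, with a gap to its neighbour over 0.829 of the whole range, where chance gives about 6. Control 3 had a neutrophil score of −0.339 against 0.662 to 0.854 in the other controls (gap 0.839 of the range). Control 4 had an endothelial score of 0.232 against 0.0184 to 0.051 (gap 0.847). Control 4 also had a keratinocyte score of 4.33 against −0.725 to −0.629 (gap 0.981). P. gingivalis 1 had a fibroblast score of 0.304 against 0.0534 to 0.0716 (gap 0.927). The log2 signal of Gsta3 was −1.14 in P. gingivalis 3 against −0.594 to −0.539 (gap 0.908), and that of Ppargc1a was 3.52 in P. gingivalis 2 against 3.4 to 3.41 (gap 0.905). Slc2a4 stood at 7.84 in control 2 against 8.06 to 8.1 (gap 0.859). As this number is near what chance gives, no cause was sought except for the keratin genes.

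The 930 probes at an unadjusted p under 0.01 were more than any other split of the arrays gave. Only 1 of the 35 splits, the real one, gave as many, and the highest other split gave 629. That is the smallest share 35 splits can give, for a test chosen after the count was seen. Chance alone is therefore less likely for this count but is not excluded. A bias by probe GC content is argued against, since the absolute rank correlation of the log2 change with GC was 0.00333, while other splits reached 0.17. Dim probes as the whole source are argued against too, since 2.44% of the brighter tested probes were at p under 0.01, where the highest other split gave 1.03%. The place on the slide stays open, as controls filled row 1 and P. gingivalis arrays row 2. Of 25 control probes 0 had p under 0.01, but this allows a share of up to 13.7%, above the 2.94% of tested probes. Slide row and an effect of P. gingivalis on the muscle, which was not tested apart from it, cannot be told apart, and both may contribute.

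The other counts gave weaker answers over the 35 splits. For the 10 lists past camera's threshold, 2 splits gave as many, the real one included, and the highest other gave 10, with P. gingivalis 3 in place of control 3. For the 2 lists past the exact test, 8 splits gave as many and the highest other gave 3. For the 35 probes well above background in 1 group only, 2 splits gave as many and the highest other gave 38. Chance cannot be excluded for these 3 counts either. No probe passed adjustment in the real split, nor in any of the 35 (highest other 0, by limma, with 3527 at an unadjusted p under 0.05).

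Control 4 alone had high keratin genes. A second list of 20 epidermal genes, written down before it was tested, had 11 tested genes, of which 8 were highest in control 4. That is a share of 0.727 where chance gives 0.125, which argues against faulty single spots as the whole source. Skin carried over with the muscle piece was tested with the same list. Its median log2 excess of 1.31 over the other 7 arrays was past the bound of 1 set in advance for skin, and Krtdap and Dmkn exceeded them by 4.4 and 5.32. Skin is therefore the candidate explanation left. The design gives no biological one for a single control, and none was tested.

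Value table columns and scanner arrays disagreed on 4 of the 8 groups. All 8 columns matched the array at their place when the slide is read column by column, so the table may have been filled in that order with titles in another. This shows how the sources differ, not which of them is right. The split by the table's labels gave 213 probes at p under 0.01 against 930 for the scanner labels. That favours neither, because the scanner labels also part the slide rows, which could raise their count. Which source carries the right groups could not be settled.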

How the results depend on the processing

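The matched value table, the value table's groups on scanner values, and the 4 arrays with the same group in both sources were chosen after the data were seen. Other alternatives were planned.

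Of the 10 lists past camera's threshold, all 10 kept their direction and call under median centring, the stricter filter, the intensity trend and array weights. Under quantile normalization 8 did, under normexp correction 4, without a filter 5 and 7 did with the matched columns of the value table. On the 4 arrays it was 5, and it was 0 with the value table as labelled or with its groups. Leaving out 1 array kept 5 to 9 of the calls and all directions.

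By limma 0 probes passed adjustment, with 3527 at an unadjusted p under 0.05. This became 14 under normexp correction, 2 without a filter, 2 with the intensity trend and 1 with the matched value table, and stayed at 0 with each array left out in turn. The 930 probes at p under 0.01 became 3556 under normexp correction, 134 in the value table, 213 with its groups and 572 on the 4 arrays, and 626 (without control 1) to 1119 (without control 3) with 1 array left out. The 4 arrays and the fits with 1 array left out hold fewer samples, and the value table's groups compare other arrays by construction. For the others the cause was not tested.

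Lists past the exact test numbered 2, and 1 under quantile normalization, normexp correction and the stricter filter, 0 in the value table, matched or not, and 0 with its groups. With 1 array left out there were 1 to 5. Lists past camera numbered 10, and 4 under normexp correction, 3 in the value table, 2 with its groups, 6 on the 4 arrays, and 0 with an estimated correlation or by fry's directional test. With 1 array left out there were 5 to 10, the fewest without P. gingivalis 1. The cause was not tested. Probes well above background in 1 group only numbered 35, and 13 with the value table's groups, 474 on the 4 arrays and 53 to 104 with 1 array left out, since fewer arrays had to meet the rule.

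For lists past camera's threshold in the reported fit or in the alternative, mean log2 changes reversed as follows. Glycolysis was −0.0227 under quantile normalization and −0.014 under normexp correction. In the value table, fatty acid oxidation was 0.0143, muscle atrophy −0.19, immediate early 0.0877, glucocorticoid response −0.0887, macrophage −0.0189, erythroid 0.211 and endothelial 0.138. With its groups on scanner values, muscle atrophy was −0.212, immediate early 0.154, glucocorticoid response −0.109, macrophage −0.033 and endothelial 0.155.

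The other lists, past the threshold in neither, changed sign 47 times over 16 lists, 24 of them with 1 array left out.

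Genes at an unadjusted p under 0.05 reversed as well. Under normexp correction Olfr316 was 0.0892, Sapcd2 0.0495, Pip5k1b 0.0279 and Col15a1 0.0567. In the value table Wee1 was −0.0274, Mmrn1 −0.0295, Mc3r −0.148, Cmtm2b −0.0624, Mras −0.0671, Gsta3 −0.0951, Six4 0.0172, Ret 0.0742, Pip5k1b 0.00022, Ucp3 −0.056, Ppard 0.0241, Foxo3 −0.0684, Col15a1 0.186, Fosb 0.184, Itgam −0.0473, Kdr 0.147, Cldn5 0.00703 and Egfl7 0.152. With its groups on scanner values Wee1 was −0.00736, Mc3r −0.16, Cmtm2b −0.00864, Mras −0.0244, Igsf1 −0.0735, Gsta3 −0.0915, Sapcd2 0.23, Ret 0.116, Pip5k1b 0.0523, Icam1 0.0527, Tbc1d1 −0.0554, Aldoa −0.0131, Gapdh −0.0346, Ucp3 −0.0626, Myl1 −0.032, Tnni2 −0.0793, Foxo3 −0.0719, Col1a2 −0.0355, Col1a1 −0.0101, Col15a1 0.392, Fosb 0.222, Fkbp5 −0.126, Itgam −0.0599, Fabp4 0.0317, Kdr 0.177, Cldn5 0.0339 and Egfl7 0.186. With the mean of all probes Itgam was −0.187. The relabelled results compare other groups by construction, and for the rest the cause was not tested.

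A block for replicate number gave 0 probes past adjustment, 700 at p under 0.01 and 12 lists past camera, the 10 in the same direction with TNF and NF-kB response and interferon response. The numbers do not pair the arrays as far as the data show: 1 of 4 controls correlated best with the P. gingivalis array of its own number. The exact list test was not run with the block, the trend or the weights. A block for slide was not run, as there was 1 slide.

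Signal over background limits the dim probes. Cxcl1, Sapcd2 and Pde8a were not well above background on any array of 1 group, so only bounds can be given for them. Mc3r, Olfr316, Col15a1, S100a8 and Il6 were well above background on only 1 or 2 arrays of 1 group, and no size is given for them. Pip5k1b and Ccl2 were so on only 3 P. gingivalis arrays, so their sizes are less certain.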

Other observations

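The tests in this part were all chosen after the data were seen.

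The 7 spike-in probes, which read RNA added from outside the sample, had a lower median signal in P. gingivalis arrays, by 0.369 before scaling (log2, two-sided exact permutation p = 0.0857) and by 0.11 after scaling (exact permutation p = 0.371). The median tested probe was lower by 0.258 before scaling.

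Genes were also grouped by the letters that begin their symbols, giving 86 families of at least 15 tested genes. Only the 34 collagen genes passed camera's adjusted threshold (mean log2 change 0.292, adjusted p = 0.00354), and they did not with an estimated correlation (p = 0.255) or by the exact permutation test (p = 0.0857). The 43 cytochrome P450 genes had a mean of 0.105 (adjusted p = 0.14) and the 177 olfactory receptor genes a mean of −0.0552 (adjusted p = 0.392).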
